A study of Mus musculus with 6 samples.

How the data were processed

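Immune cells of the central nervous system were profiled from C57BL/6 mice with experimental autoimmune encephalomyelitis (EAE), an induced autoimmune inflammation of brain and spinal cord used as a model of multiple sclerosis. Wild-type (WT) mice and mice lacking the microRNA miR-155 (KO) were sampled on days 0, 13 and 21 after induction. Per the labels, each genotype and day had 5 mice, and the cells were live, DAPI-negative, CD45-positive cells taken by flow sorting. The labels give the tissue as brain, while their protocol also names spinal cord. Each of the 6 combinations of genotype and day was 1 droplet library of 3' ends with unique molecular identifiers (UMIs). The titles of both libraries of a day share a number prefix, and other days have another one. What the prefix stands for is not stated, so day and any batch it marks cannot be told apart. Replicate numbers were not needed, since every group held 1 library.

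The deposited matrices hold raw UMI counts per gene and cell barcode, whole numbers with no normalization, over 28692 genes. Per the submitters' processing notes, Cell Ranger 2.0.2 and the mouse build mm10 were used, and the counting options are not given in the sources used here. Whether barcodes or doublets were filtered further before the counts were deposited is likewise not given in the sources used here. The files held 20030 barcodes, and their lowest UMI totals per library ran from 1490 to 2039.

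Cells with at least 200 detected genes and at most 10% mitochondrial UMIs were kept, which removed 23 barcodes for mitochondrial share and 0 for gene number. Doublets were called per library with scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells. It called 16 of 20030 cells, 3, 4, 0, 0, 5 and 4 in the WT and KO libraries of days 0, 13 and 21, where 1.77%, 1.34%, 2.91%, 2.48%, 4.50% and 3.01% were expected. The doublet call has therefore not worked, and doublets of unlike cells remain in the data. The 19991 cells kept were scaled to 10000 UMIs and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0. Mitochondrial, ribosomal protein, hemoglobin and sex-linked genes were left out of the variable genes.

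The 27 clusters were named from marker genes fixed before the data were examined. A cluster took the class with the highest marker score if at least 3 of its markers were raised 2-fold or more over the other clusters and no other class had more markers among its 10 leading genes by fold. A cluster that scored 1.5 or more for a class of another lineage as well, or that was led by the progenitor genes Elane, Mpo and Prtn3, stayed unnamed. Only the markers were fixed beforehand, and this scoring rule was set with the data in hand. The required number of raised markers was set after the clusters were seen, because an earlier rule asking for markers among the 50 leading genes left a microglial cluster of the diseased libraries unnamed. In all, 8 clusters stayed unnamed, and their shares per library are given. Cells of 9 named classes are called microglia-like, T-like and so on. Shares have exact (Clopper-Pearson) 95% binomial intervals, summed UMI counts have exact Poisson intervals and ratios of counts have exact conditional intervals. Ratios of shares have log-normal intervals. All of these cover counting error only. A count of 0 was bounded by a floor of 3 counts or by the upper end of its interval.

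UMI counts were summed per library and class, and expressed as CPM, the usual scaling of counts to the class total. Within a day, each KO library was compared with the WT library of that day in classes with 50 or more cells in both, as log2 of the ratio of CPM with a pseudocount of 1. With 1 library on each side there was no test, and a difference within a day has no replicate check. For the 24 gene lists fixed before the data were examined, members with 10 CPM or more in either library were counted as measured, and those 1.5-fold or more apart were counted. The median of each list was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

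Genotype over days was tested per class with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr) on the summed counts with day as a block, with Benjamini-Hochberg adjustment at 0.05. The libraries of other days served as replicates in this model, so an effect of genotype that changes with day adds to the residual spread. All 6 libraries entered for microglia-like, T-like, neutrophil-like and B-like cells, and the 4 of days 13 and 21 for monocyte/macrophage-like and conventional dendritic-like cells. Days were compared in microglia-like cells by the same test with genotype as covariate, with 2 libraries per day. The overlap of the day 13 and day 21 calls was set beside 20 simulations in which all libraries were drawn from the day 0 means. No group held more than 1 library, so P-values here measure how far the genotype difference varied between days. They do not measure spread between replicate libraries or between mice. Lists were tested with camera in limma 3.58.1 with its preset correlation and again with the correlation estimated from the data, with adjustment over the lists. DESeq2 1.42.0 served as the other tool. Both the gene tests and the list medians were tested on simulated data drawn from the real means and library sizes. At a true 4-fold change the genotype test recovered 99% of changed genes in T-like cells and 100% in microglia-like cells. At 2-fold it recovered 77% and 98%, with 100 genes per fold size. False calls numbered 8 and 18 among 6431 and 10185 genes. In B-like and neutrophil-like cells it recovered 94% and 100% at 4-fold, and 63% and 66% at 2-fold. The changed genes had a mean of 20 CPM or more. Their change was the same on every day, and no day effect was simulated, so weaker or varying effects are not covered.

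Sites of miR-155-5p, meaning 7-base or longer matches to its seed, were searched in the longest annotated 3' UTR of 20715 genes of GENCODE vM21, and 2623 genes had a site. The median log2 ratio of site genes with a mean of 20 CPM or more was placed among 10000 random sets matched on expression and 3' UTR length. Seeds of 11 other microRNA families were run as controls.

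Genes are named by rules fixed before the data were examined. For days, these are the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of 50 CPM or more and the same direction in both genotypes. For genotype over days they are the 10 largest in each direction. Within days 13 and 21 they are, per class, the first 6 each way among genes with 50 or more UMIs and 50 CPM or more on each day and the same direction on both days, ranked by the smaller of the log2 ratios, and for day 0 the first 6 each way in microglia-like cells. Predicted, clone-named, antigen receptor, hemoglobin, mitochondrial, ribosomal protein and sex-linked genes were left out of the ranks within days and between days, and 1 further pattern of clone names was added to them after it appeared. Always named were the miR-155 host gene, the published targets Inpp5d, Socs1 and Cebpb, Ptprc, and in T-like cells Il17a, Ifng, Csf2 and Foxp3. Of each list, the members with the largest ratios are named. The result for 1 gene that the rules named is not reported here.

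Alternatives fixed before the data were examined were 500 or more genes per cell, at most 5% mitochondrial UMIs, doublets kept, clustering at 2 times the resolution, classes from each cell's own marker score, TMM scaling or CPM without mitochondrial and ribosomal protein genes, a pseudocount of 10, DESeq2 and its size factors, no low-count filter, no day block or no genotype covariate, days 13 and 21 alone, each library left out, 8-base sites and a mean of 50 CPM for site genes. The first 2 of these were run by dropping cells from the clusters of all cells, not by clustering again. With doublets kept, the cells were clustered again, so its values also carry new class borders. In the day 13 libraries, where 0 doublets were called, they carry those borders alone. Added after the data were seen were the removal of cells with 3 or more UMIs of each of 2 lineages (10 or more for phagocyte markers), the removal of the highest doublet scores, other ways to count the unnamed clusters, and T-like cells without their Cd8a-led cluster. Software was Python 3.11.15 with anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.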

Results

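The series asked what the microRNA miR-155, which is induced in activated leukocytes, does in the immune cells of the inflamed central nervous system. CD45-positive cells were profiled by droplet RNA sequencing in wild-type (WT) and miR-155 knockout (KO) mice with experimental autoimmune encephalomyelitis (EAE), on days 0, 13 and 21. There was 1 library per genotype and day, 6 in all, each from 5 mice according to the labels. The WT libraries of days 0, 13 and 21 held 8566827, 20298806 and 24243660 unique molecular identifiers (UMIs) over 2215, 3640 and 5630 barcodes. The KO libraries held 6321841, 18066205 and 15504139 UMIs over 1681, 3101 and 3763 barcodes. The median cell had 3236, 4368.5 and 3339 UMIs in the WT libraries and 3210, 4341 and 3019 in the KO libraries. Every contrast of KO with WT within a day sets 1 library against 1 library and has no replicate check. Its intervals are 95% intervals that cover counting error only.

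The host gene of miR-155, Mir155hg, was read first in every library. It had 2, 45 and 59 UMIs in the WT libraries of days 0, 13 and 21, which is 0.234 CPM (0.028 to 0.846), 2.22 CPM (1.62 to 2.97) and 2.44 CPM (1.85 to 3.14). The KO libraries had 0, 0 and 1 UMIs. A floor of 3 counts puts the KO level below 0.477 CPM on day 0 and 0.166 CPM on day 13, and the single UMI of day 21 is 0.065 CPM (0.002 to 0.36). On days 13 and 21 the gene was thus lower in the library labelled KO, and on day 0 its level was too low to tell. The labels do not say which part of the host gene the KO allele removes, so its level need not follow that of the microRNA. Of the named classes in WT libraries, conventional dendritic-like cells had the most UMIs of the gene, with 19 on day 13 (13.6 CPM, 8.20 to 21.3) and 14 on day 21 (8.78 CPM, 4.80 to 14.7). Gamma-delta T-like cells had 1 UMI on each of these days, among 23 and 44 cells, too few to rank. T-like cells had 4.34 and 2.96 CPM on these days, and microglia-like and neutrophil-like cells had 0 UMIs in all 6 libraries.

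The first comparison asked how the makeup of the CD45-positive cells differed between genotypes. On day 21, the last day sampled, the KO library was rich in microglia, the resident macrophages of the brain, and poor in T cells and monocyte-derived cells, which enter from the blood. Microglia-like cells were 41.2% of KO and 8.77% of WT cells, a ratio of 4.69 (4.28 to 5.15). T-like cells were 4.61% of KO and 20.1% of WT cells, so their share was 4.37-fold higher in WT. Monocyte/macrophage-like cells were 5.30% against 13.6%, a KO to WT ratio of 0.391 (0.336 to 0.454). Conventional dendritic-like cells, which present antigen to T cells, had a ratio of 0.667 (0.549 to 0.811).

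On day 13 the direction was different for 3 of these 4 classes. Microglia-like cells were 14.1% of KO and 25.7% of WT cells, a ratio of 0.547 (0.494 to 0.607). Monocyte/macrophage-like cells were 19.97% against 17.8%, a ratio of 1.12 (1.02 to 1.24), and conventional dendritic-like cells were 6.78% against 4.68%, a ratio of 1.45 (1.19 to 1.76). T-like cells were again lower in the KO library, at 7.07% against 9.77%, a ratio of 0.723 (0.616 to 0.85). This ratio became 0.97 when the mixed T clusters were counted as T-like, an alternative chosen after seeing the data, and the mixed T and phagocyte cluster held 8.49% of KO and 4.27% of WT cells on day 13. B-like cells were higher in KO on both days, with ratios of 1.71 and 2.37, as were plasmacytoid dendritic-like cells, a source of type I interferon, with ratios of 2.38 and 1.70. NK-like cells, innate cytotoxic lymphocytes, had ratios of 2.47 on day 13 and 0.956 on day 21, and neutrophil-like cells 0.622 and 0.926. On day 0 microglia-like cells were 71.9% of KO and 60.9% of WT cells, a ratio of 1.18 (1.13 to 1.24), and T-like cells were 3.52% against 5.03%. These are shares of sorted cells, so a higher share of 1 class lowers the others, and the gate on CD45, which microglia carry at a lower level than blood cells, can set them. Cells of clusters left unnamed were 29.6% of WT and 19.2% of KO cells on day 21, and 19.1% and 21.3% on day 13.

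**Figure D1:**
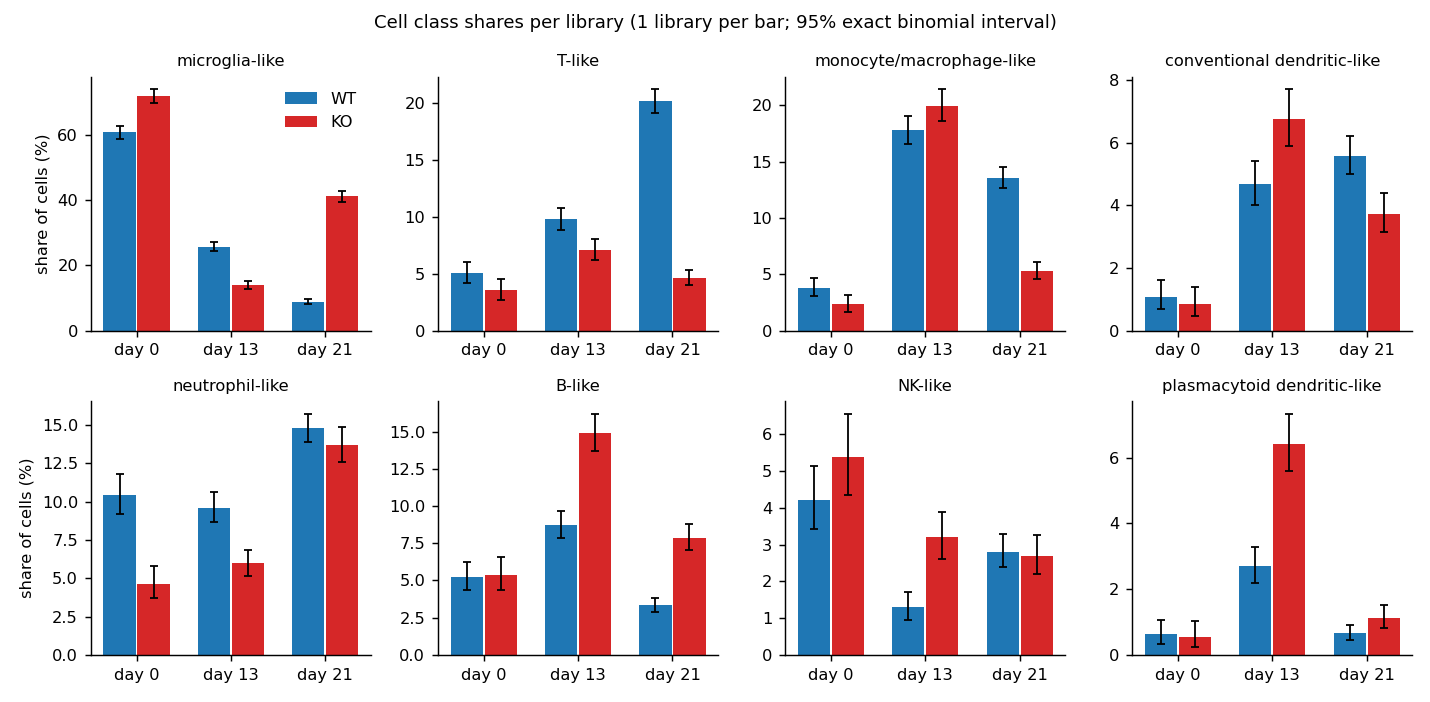
Share of cells (%) of 8 cell classes in each library, with 1 panel per class, bars for WT (blue) and KO (red) on days 0, 13 and 21, and exact 95% binomial intervals for counting error. Microglia-like cells were 41.2% of the day 21 KO library and 8.77% of the WT library.

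Within microglia-like cells on day 21, genes of resting microglia were higher in the KO library, and genes induced by interferons, of antigen presentation and of chemokines were lower. Of the 16 measured homeostatic genes, 8 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of KO to WT of 0.56. Fcrls, a microglial Fc receptor-like gene, was 4.45-fold higher (log2 2.15). The fructose transporter gene Slc2a5 was 2.11-fold higher, the purinergic receptor gene P2ry12, used by resting microglia to sense ATP, 1.89-fold, and the orphan receptor gene Gpr34 2.06-fold. Of 15 interferon-gamma response genes, 14 were lower by 1.5-fold or more (median -1.38). The interferon-inducible GTPase genes Iigp1 and Gbp2 were 5.13-fold and 4.25-fold higher in WT, Ciita, the master regulator of MHC class II transcription, 6.17-fold, and Cxcl10, a chemokine that draws T cells, 4.03-fold. Of 10 MHC class II genes, which present peptides to CD4 T cells, 9 were lower (median -1.41), among them Cd74, at 2.82-fold, and H2-Aa, at 2.75-fold higher in WT. Of 18 type I interferon response genes, 16 were lower (median -1.01), with Irf7, a transcription factor of this response, 2.75-fold higher in WT. Of 10 chemokines, 8 were lower (median -1.05), led by the T cell attractant Ccl5 (log2 -2.03), while Ccl3 was higher (log2 0.51). MHC class I genes had a median of -0.44 with 4 of 13 lower.

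The median of the homeostatic list lay at percentile 100 of 10000 random lists matched on expression, whose middle 95% ran from -0.26 to 0.22, and those of the interferon-gamma, type I interferon, MHC class II, chemokine and MHC class I lists at percentile 0. The median over all genes was 0.10 in this class and on this day, and list values are read against the matched random lists, which share it. The libraries drew their microglia-like cells from different clusters. The cluster led by Olfml3, Ltc4s and Cd81 held 77.7% of KO and 38.5% of WT cells of the class, that led by Ccl12, Hcar2 and Ccl7 held 8.5% and 58.8%, and that led by P2ry12, Fcrls and Jun held 11.5% and 0.0%. Markers of other cells differed too. T cell markers summed to 20.9 CPM in KO and 103 CPM in WT microglia-like cells, monocyte/macrophage markers to 190 and 390, and border-associated macrophage markers to 43.2 and 6.81 CPM.

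Published miR-155 targets had a median log2 ratio of 0.40 in the same cells, at percentile 99.88, with 6 of 19 higher and 1 lower. The transcription factor gene Maf was 2.07-fold higher in KO, and Socs1, a brake on cytokine signalling, was 2.14-fold higher in WT. Fos and Csf1r belong to the target list and also to the dissociation and the homeostatic list. Mir155hg had 0 UMIs in these cells, and of 7592 genes 893 were 1.5-fold or more higher in KO and 390 lower. Genes of alternatively activated phagocytes had a median of 0.58, with Mrc1, the mannose receptor, at 19.6 CPM in KO and 3.40 in WT, but the chitinase-like gene Chil3 at a log2 ratio of -1.70. The genes induced by tissue dissociation were also higher, with 8 of 15 at 1.5-fold or more and a median of 0.59 at percentile 100. Genes of disease-associated microglia had a median of -0.08 (percentile 12.6) and 5 of 17 lower, among them the lipid carrier gene Apoe (log2 -1.13) and the phagocytic receptor gene Axl (log2 -1.07). Complement genes had a median of -0.04 and cell cycle genes 0.15.

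On day 13 the interferon-gamma and MHC class II lists of microglia-like cells had medians of 0.23 (percentile 99.96) and 0.44 (percentile 100), with 0 members 1.5-fold apart in either list. H2-Eb1 was 1.40-fold higher in KO. The homeostatic median was -0.13 (percentile 0.01) and the type I interferon median -0.01. Chemokines went both ways, with Ccl7, a monocyte attractant, 2.56-fold higher in KO and Cxcl13, a B cell attractant, 3.02-fold higher in WT. The dissociation genes were again higher, with 8 of 14 and a median of 0.69, led by Dusp1 at 3.15-fold and Fos at 2.76-fold. The published targets had a median of 0.01. The Ccl12-led cluster held most of the class in both libraries, 82.1% in KO and 72.7% in WT, and neutrophil markers were lower in the KO cells, with a ratio of 0.566. On day 0 the differences were small except for interferon genes and chemokines. Of 11 type I interferon genes, 5 were lower (median -0.25, percentile 0.01), among them Irf7 (log2 -1.25), and the chemokine median was -0.35. Neutrophil and T cell markers in these day 0 cells had KO to WT ratios of 0.662 and 0.560.

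**Figure D2:**
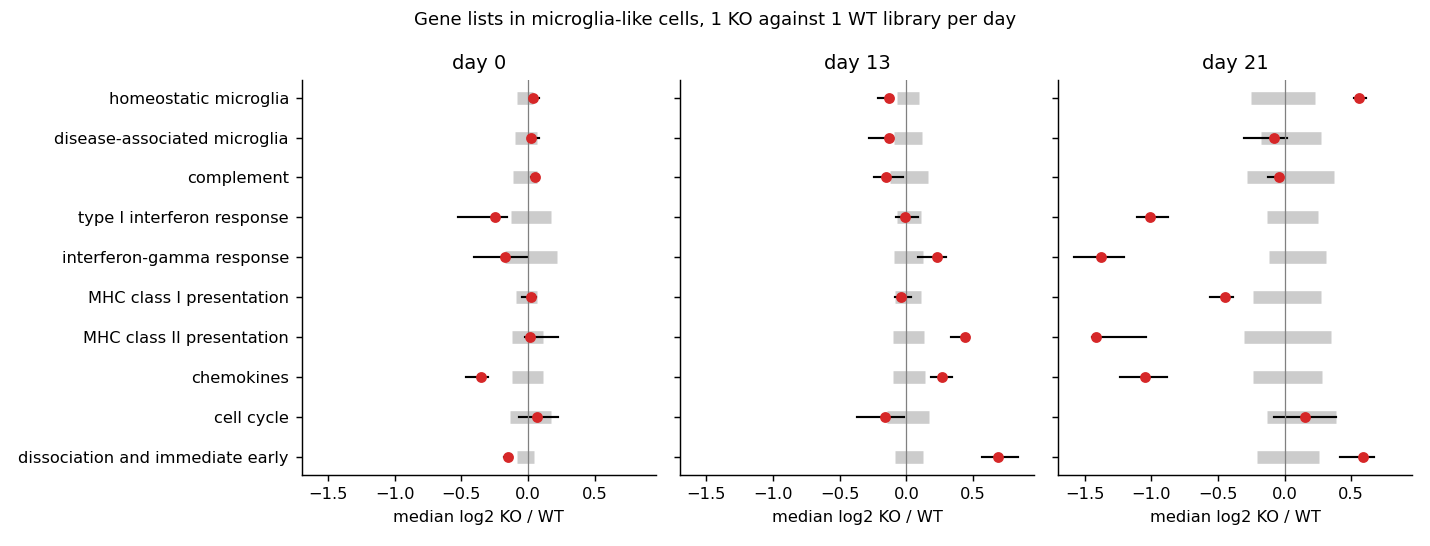
Median log2 ratio of KO to WT CPM of 10 gene lists in microglia-like cells, with 1 panel per day. Dots are list medians, black lines their 95% counting intervals and grey bands the middle 95% of 10000 matched random lists. On day 21 the interferon-gamma list lay at -1.38 and the homeostatic list at 0.56.

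Genes were named by rule in microglia-like cells among those with the same direction on days 13 and 21. The highest in KO were Klf2, a transcription factor of quiescence, at 2.94-fold (2.47 to 3.50) on day 13 and 2.00-fold (1.67 to 2.41) on day 21, the immediate early genes Fos, Jun and Dusp1, the mRNA decay factor gene Zfp36, and Hist4h4. Lower in KO were Chil3, with ratios of 0.521 (0.406 to 0.662) and 0.297 (0.213 to 0.415), Ly6i, Apoe, Ccl5, Axl and S100a6. On day 0 the highest was the heat shock gene Hspa1b at 2.48-fold (1.96 to 3.16), with Impact, Gstp1, Snrpg and Hspb1 also named. The lowest on day 0 were Mid1 (log2 -1.43), the neutrophil granule genes Camp, Ngp and S100a9, Ccl2 and Ccnd3. The phosphatase gene Inpp5d, encoding SHIP1 and a known miR-155 target, had log2 ratios of 0.07, -0.24 and 0.24 on days 0, 13 and 21, and the target Cebpb 0.37, 0.38 and -0.13. Ptprc, which encodes CD45, the sorted antigen, had -0.02, -0.02 and 0.25.

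With the 3 days as replicates of the genotype contrast, edgeR's quasi-likelihood test called 1 gene higher and 2 lower in KO microglia-like cells, of 10386 tested. Cxcl13 fell by 1.74 on the log2 scale (SE 0.196, adjusted p = 0.00532), with the direction in 2 of 3 days. Chil3 fell by 1.24 (SE 0.184, adjusted p = 0.0454) and Hspa1b rose by 1.25 (SE 0.188, adjusted p = 0.0454), both in 3 of 3 days, all Benjamini-Hochberg adjusted in edgeR. At an unadjusted p under 0.05 there were 412 genes, and DESeq2 called 0. Of the 18 type I interferon genes, 0 passed over all genes and 8 fell when adjusted over the list alone, with a median of -0.53. The list was called lower by camera (adjusted p = 3.85e-10), and p = 0.205 with an estimated correlation. The interferon-gamma list was called lower in the same way (adjusted p = 6.97e-06, and p = 0.267 with an estimated correlation), with 0 of 15 genes past the threshold over all genes or adjusted over the list alone. The dissociation list was called higher (adjusted p = 4.97e-05, and p = 0.19 with an estimated correlation), with 1 of 17 genes past the threshold, over all genes and adjusted over the list alone. Of 21 published miR-155 targets, 0 passed over all genes or adjusted over the list alone, with a median of 0.16. Camera gave these targets an adjusted p of 0.0587, and p = 0.193 with an estimated correlation. The count of 3 became 14, 129 and 37 without the KO libraries of days 0, 13 and 21, and 14, 127 and 38 without the WT libraries, where leaving out 1 library also removes its day from the contrast.

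In T-like cells, genes of cytotoxic lymphocytes were lower in the KO libraries on all 3 days, and genes of naive T cells were higher on day 21. The class held 59, 219 and 173 KO cells and 111, 355 and 1130 WT cells on days 0, 13 and 21. Of all 7608 genes measured in it on day 0, 1495 were 1.5-fold or more higher in KO and 2076 lower. Of the measured cytotoxicity genes, 7 of 11 were 1.5-fold or more lower on day 0 (median log2 -1.17), 10 of 10 on day 13 (-1.07) and 9 of 10 on day 21 (-1.29), each at percentile 0. Gzma, encoding the granule protease granzyme A, was 28.4-fold (19.8 to 42.3) higher in WT on day 13, at 890 against 31.3 CPM. On day 21 it had 0 UMIs in KO and 1856 in WT, at least 105-fold higher in WT against a floor of 3 counts in the KO class total. Granzyme K (Gzmk) was 3.25-fold higher in WT on day 13 and 11.4-fold (6.33 to 22.9) on day 21, granzyme B (Gzmb) 3.67-fold on day 21, and Ccl5 4.05-fold and 3.55-fold. Of 9 naive T cell genes, 7 were higher on day 21 (median 0.90, percentile 100). The lymph node homing receptor gene Ccr7 was 2.60-fold higher in KO and the transcription factor gene Lef1 2.36-fold. Activation genes were lower on days 13 and 21 (medians -0.44 and -0.40), among them the checkpoint receptor gene Pdcd1 (log2 -1.33 and -1.07).

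Regulatory T cell genes had a median of 0.61 on day 13 (6 of 11 higher, percentile 100) and -0.01 on day 21. Foxp3, which specifies regulatory T cells, was 1.76-fold (1.236 to 2.501) higher in KO on day 13 and 1.42-fold (0.971 to 2.02) on day 21, an interval that includes no difference. Th17 genes had medians of 0.29 (percentile 92.2) and -0.53 (percentile 0.78), and Th1 genes -0.14 and -0.13, where the Th1 value of day 21 turned to 0.027 with classes from each cell's own marker score. Ifng, the interferon-gamma gene, had a ratio of 1.91 (1.35 to 2.70) on day 13 and 1.04 (0.636 to 1.62) on day 21. Il17a was measured with a wide interval at this depth, with 15 UMIs in KO and 14 in WT on day 13 (ratio 1.80, 0.81 to 4.03) and 0 and 6 on day 21. Csf2, the GM-CSF gene, had 2 and 0 UMIs on day 13 and 2 and 5 on day 21. Cell cycle genes had a median of -0.65 on day 21, with the proliferation marker Mki67 3.26-fold higher in WT. Their day 13 median of 0.17 turned to -0.027 with doublets kept, -0.007 at 2 times the resolution and -0.51 with classes from each cell's own marker score. No cell of either day 13 library was called a doublet, so the first of these values reflects the new clustering of that alternative.

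Beside these lists, the Cd8a-led cluster held 20.8% of WT and 2.7% of KO T-like cells on day 13, and 37.0% and 7.5% on day 21. The level of Cd8a, encoding a chain of the CD8 co-receptor, was 2.98-fold and 2.73-fold higher in WT, and that of Cd4 had KO to WT ratios of 0.807 (0.637 to 1.02) and 1.38 (1.04 to 1.80), the latter turning to a log2 ratio of -0.049 without the Cd8a-led cluster, an alternative chosen after seeing the data. NK cell markers, a list that includes Gzma, summed to 53.2 CPM in KO and 950 in WT on day 13, and 35.0 and 703 on day 21. Microglia markers in T-like cells were at 473 CPM in KO and 205 in WT on day 21. Neutrophil markers in T-like cells had KO to WT ratios of 0.606, 0.504 and 0.766 on days 0, 13 and 21, and monocyte/macrophage markers 0.507, 0.692 and 0.608. MHC class II genes, which mouse T cells hardly express, had a median of 1.29 on day 13 and -0.36 on day 21 in these cells, and homeostatic microglia genes 1.21 on day 21. The MHC class II value of day 21 turned to 0.068 with classes from each cell's own marker score and to 0.75 with the highest doublet scores removed, the latter chosen after seeing the data. Besides Gzma, Gzmk, Ccl5 and Cd8a, the rule named Klrc1 and Ly6c2 as lower on both days, and Ecm1, Pdk1, Jun, Cst3 and Cd81 as higher. Cst3 and Cd81 turned on both days with classes from each cell's own marker score, to log2 ratios of -0.14 and -0.13 on day 13 and -0.004 and -0.22 on day 21. On day 13 Cst3 also turned to -0.28 with cells of 2 lineages removed, chosen after seeing the data, and Cd81 to -0.054 with doublets kept and -0.31 at 2 times the resolution. The targets Inpp5d and Socs1 had log2 ratios of -0.09 and 0.55 on day 13 and of -0.04 and -0.40 on day 21, and Ptprc -0.19 and 0.17.

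Over the 3 days, edgeR's test called 8 genes higher and 16 lower in KO T-like cells, of 6776 tested, and each of the 24 had its direction in 3 of 3 days. Genes of cytotoxic lymphocytes led those that fell. Gzma fell by 5.38 on the log2 scale (SE 0.342, adjusted p = 9.30e-07), a fitted size that depends on the prior count. The NK receptor gene Klrc1 fell by 2.59 (SE 0.263, adjusted p = 1.91e-04), Gzmk by 2.30 (SE 0.270, adjusted p = 8.84e-04) and Ccl5 by 1.99 (SE 0.101, adjusted p = 9.24e-08), all by edgeR with Benjamini-Hochberg adjustment. Wdr95, the gamma-delta receptor gene Tcrg-C2, Ccl4, Ly6c2 and the myeloid genes Chil3 and Ngp fell too, the last 2 beside lower neutrophil and monocyte/macrophage markers in these cells on all 3 days. The other 6, named after their values were seen, were Pdcd1, Klrk1, Cd8a, Nkg7, Ctla2a and Ctsw. The 8 that rose included Jun by 0.72 (SE 0.134, adjusted p = 0.0361 in edgeR), Apoe by 0.80, and Rps27, Rps29, Rps28, Rps27rt and Gm10076 by 0.62 to 1.08. Counts of the ribosomal protein genes among them are uncertain where reads also match close copies elsewhere, which was not measured. Beside Jun, the dissociation list had a median of 0.29 and was called higher by camera (adjusted p = 0.00349, and p = 0.128 with an estimated correlation), with 1 of 13 genes rising, over all genes and adjusted over the list alone. DESeq2 called 22 genes, of which 18 were among the 24.

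Of the 10 cytotoxicity genes tested, 6 fell over all genes and 10 when adjusted over the list alone. The list was called lower by camera (adjusted p = 1.59e-12), and p = 0.0159 with an estimated correlation, which is an adjusted p of 0.366 over the lists. Of the 9 naive T cell genes, 0 passed over all genes and 7 rose when adjusted over the list alone (camera adjusted p = 3.39e-05, and p = 0.131 with an estimated correlation). When T-like cells were taken without the Cd8a-led cluster, an alternative chosen after seeing the data, 23 genes passed. These included 6 of the 16 that fell, with Gzma at -4.64 and Nkg7 at -0.55, and not Ccl5 at -0.93 (adjusted p = 0.174 in edgeR) or Cd8a at -0.43. Tcrg-C2, at -3.49 (adjusted p = 0.0906 in edgeR), and Ccl4, Pdcd1 and Klrk1, at -1.31, -0.88 and -0.86, did not pass either, and Wdr95 was not tested. Apoe turned to -0.19 once cells with markers of 2 lineages were removed and to -0.46 with classes from each cell's own marker score, and Klrk1 to 0.16 with doublets kept. The count of 24 became 47, 109 and 54 without the KO libraries of days 0, 13 and 21, and 69, 115 and 15 without the WT libraries.

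**Figure D3:**
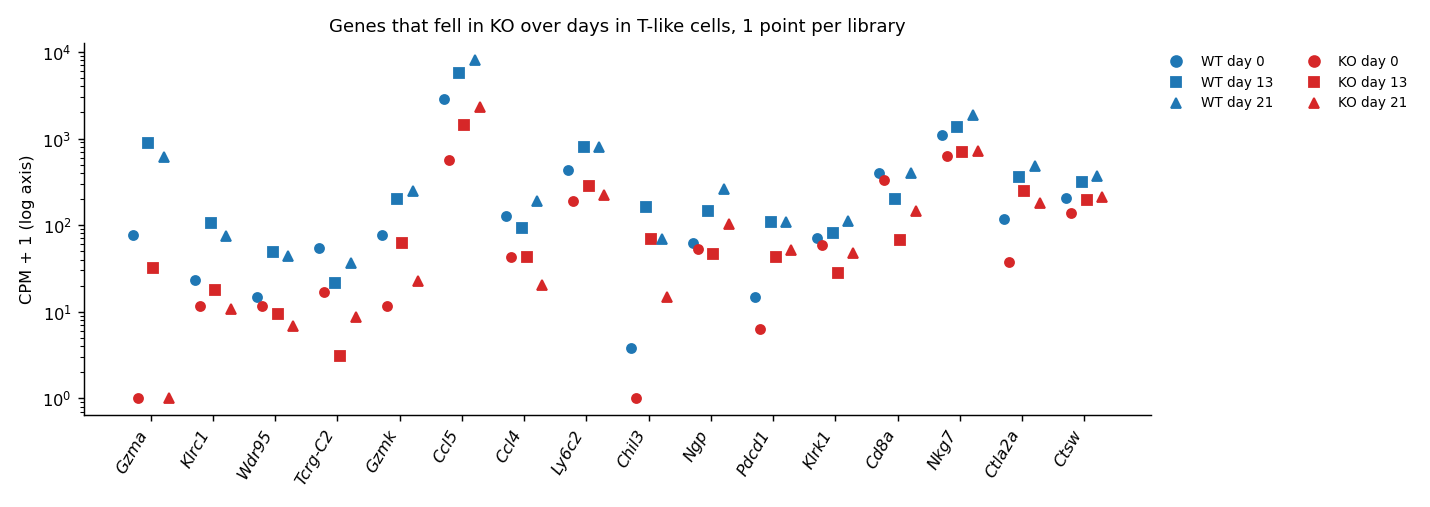
Level (CPM + 1, log axis) in T-like cells of the 16 genes that fell in KO over days, with 1 point per library, circles for day 0, squares for day 13 and triangles for day 21, WT in blue and KO in red. They include Gzma, at 890 CPM in WT and 31.3 CPM in KO on day 13.

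Monocyte/macrophage-like cells of the day 21 KO library had lower interferon-gamma, chemokine and inflammatory cytokine genes. Of 15 interferon-gamma genes, 12 were lower (median log2 -1.29), with Cxcl10 9.79-fold and Cxcl9 4.63-fold higher in WT. Of 10 chemokines, 9 were lower (median -1.87), and Ccl7 was 16.4-fold higher in WT, while Ccl3 was higher in KO (log2 0.86). Of 13 NF-kB and inflammatory cytokine genes, 9 were lower (median -1.02), among them Nos2, which makes nitric oxide (log2 -2.17), and Il1b, 2.57-fold higher in WT. These lists lay at percentile 0. On day 13 the medians were -0.15, 0.44 and -0.02. Homeostatic microglia genes had a median of 0.88 in the KO cells of day 21, beside the higher microglial share of that library. The cluster led by Cxcl10, Irg1 and Cxcl9 held 25.2% of WT and 4.0% of KO cells of this class on day 21, and that led by F13a1, Fn1 and Ccr2 39.1% and 68.8%. Named lower on both days were the granule genes Camp and Ngp, Iigp1, Bcl3, Stx11 and Herc6, and named higher Fos, Tsc22d3, Cox17, Eif4a2 and Bola2. Socs1 had log2 ratios of -0.30 and -1.87. Over days 13 and 21, with 4 libraries, edgeR called 0 of 9006 genes, with 259 at an unadjusted p under 0.05, and DESeq2 0. Of the interferon-gamma genes, 5 fell when adjusted over the list alone (camera adjusted p = 4.58e-07, and p = 0.325 with an estimated correlation).

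Conventional dendritic-like cells, the named class with the most Mir155hg UMIs in WT, had chemokine medians of opposite sign on the 2 days. On day 13 chemokines were higher in KO, with 6 of 12 (median log2 0.82, percentile 100), among them Cxcl2, a neutrophil attractant, at 6.86-fold and Ccl4 at 2.68-fold. NF-kB and cytokine genes were higher (median 0.54), and cell cycle genes were lower, with 12 of 17 (median -0.98), led by Rrm2, a subunit of the enzyme that makes deoxynucleotides, 7.80-fold higher in WT. This median turned to 0.55 with the called doublets kept, although no cell of either day 13 library was called a doublet. On day 21 chemokines had a median of -0.85, with Cxcl9 3.66-fold higher in WT, and interferon-gamma genes -1.14 (11 of 15 lower, percentile 0). T and NK cell genes were also lower in these cells, with Nkg7 at -1.78 and -3.81 and Cd3g at -1.20 and -1.34 on days 13 and 21, and homeostatic microglia genes had a median of 0.68 on day 21. Slpi, Gatm, Ms4a4b and Cd3d were the other genes named lower, and Il4i1, Pmaip1, Zfp36, Il13ra1 and Bmp2k were named higher. On day 13 Slpi turned to 1.17 at 2 times the resolution and to 0.78 with classes from each cell's own marker score. The target Cebpb had log2 ratios of 0.86 and -1.10. Over both days edgeR called 0 of 7879 genes, with 282 at an unadjusted p under 0.05, and DESeq2 0. The cell cycle list was called lower (camera adjusted p = 3.32e-07, and p = 0.248 with an estimated correlation), with 4 genes when adjusted over the list alone.

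Neutrophil-like cells had lower type I interferon genes in KO, with 8 of 17 on day 13 (median log2 -0.46) and 11 of 15 on day 21 (-0.87), and the ubiquitin-like modifier gene Isg15 at -0.75 and -0.87. Sptssa, Lmo1, Klhdc4, Orm1 and Uqcrfs1 were the other genes named lower on both days, and Prok2, Acvrl1, Pet100, Tnfaip2, Myeov2 and Gzma those named higher. Gzma, a gene of cytotoxic lymphocytes, had a log2 ratio of 0.64 on day 21, which turned to -3.24 once cells with markers of 2 lineages were removed, and its day 13 ratio turned to -1.46 at 2 times the resolution and -1.82 with classes from each cell's own marker score. Over days edgeR called 0 of 5556 genes, with 268 at an unadjusted p under 0.05, and DESeq2 0. Of the type I interferon genes, 9 fell when adjusted over the list alone (camera adjusted p = 1.4e-05, and p = 0.0467 with an estimated correlation, an adjusted p of 0.761). The median over all genes was -0.18 on day 21 in these cells, and TMM scaling shifted it by 0.19, so the day 21 values are read against that median. B-like cells had lower interferon-gamma genes, with medians of -0.57 on day 13 and -0.89 on day 21, and Xbp1, a transcription factor of plasma cells, at -0.86 and -0.66. Bet1l, Ubn1, Txndc5, Tmem30a and Serpinb1a were also named lower on both days, and Ifnar1, a chain of the type I interferon receptor, at 0.98 and 1.26, Mak16, Junb, Rcc2, Marcksl1 and Ktn1 higher. On day 21 Xbp1 turned to 0.50 and Txndc5 to 0.42 with classes from each cell's own marker score. MHC class II genes of B-like cells had a median of 0.09 on day 21, where the median over all genes was 0.20, and this turned to -0.06 with TMM scaling, which shifted all genes by -0.15. Over days edgeR called 1 of 5661 genes, the histone gene Hist1h2ap (log2 2.94, SE 0.437, adjusted p = 0.00904), with 255 at an unadjusted p under 0.05, and DESeq2 called 0. Without the KO libraries of days 0, 13 and 21 the count became 10, 85 and 54 in neutrophil-like cells and 20, 23 and 11 in B-like cells, and without the WT libraries 5, 91 and 52 and 20, 16 and 11.

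A further comparison asked whether genes with a miR-155 seed match in their 3' UTR were higher in KO cells. With sites of 7 bases or more, no class and day had a median above the random range by more than counting error. In T-like cells the 669 site genes measured on day 13 had a median log2 ratio of 0.01, at percentile 97.3 of 10000 matched sets, whose middle 95% ran from -0.05 to 0.01, and 0 of 11 control seeds stood as high. On day 21 the T-like median was 0.04, at percentile 81.7, again above all 11 controls, and on day 0 it was at percentile 94.4. Microglia-like cells had percentiles of 33.7, 47.1 and 62.1 on days 0, 13 and 21, monocyte/macrophage-like cells 67.3 and 14.2, and conventional dendritic-like cells 86.7 and 35.9 on days 13 and 21. Over days, camera gave p = 0.211 for site genes in T-like cells and p = 0.0656 with an estimated correlation, and p = 0.395 and 0.390 in microglia-like cells. The T-like median of day 21 turned to -0.01 with classes from each cell's own marker score, at percentile 51.8, and was 0.09 at percentile 98.1 with 8-base sites only. On day 13 the T-like median was at percentile 99.05 with doublets kept, at a value of -0.02, and at 98.2 with TMM scaling. With 8-base sites only, conventional dendritic-like cells had medians of 0.06 (percentile 97.6) on day 13 and 0.04 (percentile 96.1) on day 21. In data simulated for microglia-like cells of day 21, site genes raised 1.1-fold were placed at percentile 100, and no other class or day was simulated for site genes. Over days, the medians of the published targets ran from -0.07 in neutrophil-like to 0.23 in T-like cells. They were -0.02 in conventional dendritic-like and -0.005 in monocyte/macrophage-like cells.

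The last comparison asked how microglia-like cells of both genotypes differed between days, with genotype as covariate and 2 libraries per day. From day 0 to day 13 interferon-inducible and antigen presentation genes rose and genes of resting microglia fell. The class held different clusters on the 2 days. The P2ry12-led cluster held 96.5% of WT and 90.6% of KO microglia-like cells on day 0 and 0.1% and 0.2% on day 13, when the Ccl12-led cluster held 72.7% and 82.1%, against 0.6% and 0.1% on day 0. Of 10386 genes, 1783 rose and 1491 fell by edgeR's quasi-likelihood test, and DESeq2 called 1000 and 455. Iigp1 rose by 8.95 on the log2 scale (SE 0.702, adjusted p = 7.73e-07 in edgeR), the complement gene C4b by 7.44, Gbp4 by 7.41, the cytokine trap gene Il18bp by 7.17, Cd74 by 6.98, Zbp1, a nucleic acid sensor, by 6.97, and H2-Eb1, H2-Aa, Gbp2 and Ly6a by 6.54 to 6.86. Klf4 fell by 4.84 (SE 0.440, adjusted p = 2.83e-06 in edgeR), Fosb by 4.08, Klf2 by 3.74, Fos by 3.41, Hspa1a by 3.38 and Atf3 by 3.31, and the other genes named were Adamts1, Tmx4, Hpgd and Dusp1. Of these, Fosb, Fos, Hspa1a, Atf3 and Dusp1 are also among the genes induced by tissue dissociation.

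All 16 homeostatic genes fell, with camera giving an adjusted p of 1.44e-07, and p = 0.263 with an estimated correlation. All 18 type I interferon genes rose (adjusted p = 6.57e-16, and p = 0.146 with an estimated correlation), as did all 15 interferon-gamma genes (adjusted p = 4.35e-11, and p = 0.168 with an estimated correlation). Of 11 MHC class II genes, 9 rose and 1 fell (adjusted p = 7.95e-06, and p = 0.212 with an estimated correlation), and of 13 MHC class I genes 12 rose (adjusted p = 1.72e-09, and p = 0.159 with an estimated correlation). Of 18 cell cycle genes, 14 rose and 1 fell (adjusted p = 1.84e-08, and p = 0.0518 with an estimated correlation). Of 17 genes of disease-associated microglia, 10 rose and 2 fell (adjusted p = 0.00239, and p = 0.174 with an estimated correlation). Of 17 dissociation genes, 15 fell (adjusted p = 2.47e-10, and p = 0.103 with an estimated correlation). The published targets went both ways, with 3 of 21 rising and 7 falling (camera adjusted p = 0.398). Adjusted over the list alone, the counts were the same for the homeostatic, interferon and MHC lists. They were 15 up and 1 down for the cell cycle genes, 10 up and 3 down for the disease-associated genes, 16 down for the dissociation genes and 3 up and 8 down for the targets. Monocyte/macrophage markers in microglia-like cells were at 78.4 CPM in WT and 54.3 in KO on day 0, and at 527 in both on day 13.

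Between days 0 and 21, 951 genes rose and 483 fell, with Cxcl13 rising most, by 9.85 (SE 0.384, adjusted p = 7.17e-09 in edgeR). It was followed by Iigp1, C4b, Cd74, H2-Aa, H2-Eb1, H2-Q7, H2-Ab1, Zbp1 and H2-Q6, which rose by 5.12 to 6.85. The lowest were Klf2, at a fall of 3.47, Klf4, Fosb, Dusp1, Atf3, Fos, Tmx4, Upk1b, Jun and Adamts1. Of the homeostatic genes, 7 of 16 fell, and 9 when adjusted over the list alone (camera adjusted p = 5.08e-05, and p = 0.352 with an estimated correlation). All 18 type I interferon and all 15 interferon-gamma genes rose on day 21 as well (adjusted p = 2.28e-18 and 1.03e-10, and p = 0.13 and 0.175 with an estimated correlation). Of the 17 dissociation genes, 15 fell, over all genes and adjusted over the list alone (adjusted p = 5.16e-11, and p = 0.0954 with an estimated correlation). DESeq2 called 534 genes risen and 116 fallen. From day 13 to day 21, 72 genes rose and 118 fell, and DESeq2 called 32 and 44. Between these days the Ccl12-led cluster went from 72.7% to 58.8% of WT and from 82.1% to 8.5% of KO microglia-like cells, and the Olfml3-led cluster from 20.2% to 38.5% and from 13.1% to 77.7%. Gbp4 fell by 2.69, Il18bp by 2.27, Iigp1 by 2.10 and Gbp2 by 2.07, followed by Ifi47, Cyp4f18, Zbp1, Mnda, Ms4a6c and Cd300lf. Cxcl13 rose by 2.33 (SE 0.203, adjusted p = 2.39e-04 in edgeR), Hspa1a by 2.10, Fcrls by 1.71 and Gpr34 by 1.28, and Hpgd, Adamts1, Fscn1, Sox4, Hist1h1c and the neutrophil gene Retnlg rose too. Of 15 interferon-gamma genes, 12 fell, and 14 when adjusted over the list alone (camera adjusted p = 4.80e-08, and p = 0.214 with an estimated correlation). Of the homeostatic genes 3 rose, and 11 when adjusted over the list alone (adjusted p = 2.36e-06, and p = 0.294 with an estimated correlation). The dissociation genes moved with them, with 2 of 17 rising, and 12 when adjusted over the list alone (adjusted p = 1.09e-06, and p = 0.15 with an estimated correlation).

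Both day 13 and day 21 were set against the same day 0 libraries. Of the genes called, 864 rose on both days and 431 fell on both, where independent lists would share 163 and 69.3. In 20 simulations of unchanged later groups against the day 0 means, 0.25 and 0.6 genes on average were called for days 13 and 21 and 0.05 shared, too few calls to set beside this overlap. Over all genes tested, 62.8% had the same sign on both days in the simulations and 80.1% in the data. Each side of a split of the 2 control libraries would hold 1 library, so they were not split, and part of the excess may come from the shared controls. The libraries of a day also shared a title prefix, so day and any batch it marks cannot be told apart. Without the KO or the WT library of day 0 the total of 3274 for day 13 became 1961 or 1275, and the 1434 for day 21 became 742 or 563. The 190 between days 13 and 21 became 108 and 104 without the KO libraries of these days, and 540 and 1360 without the WT libraries.

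**Figure D4:**
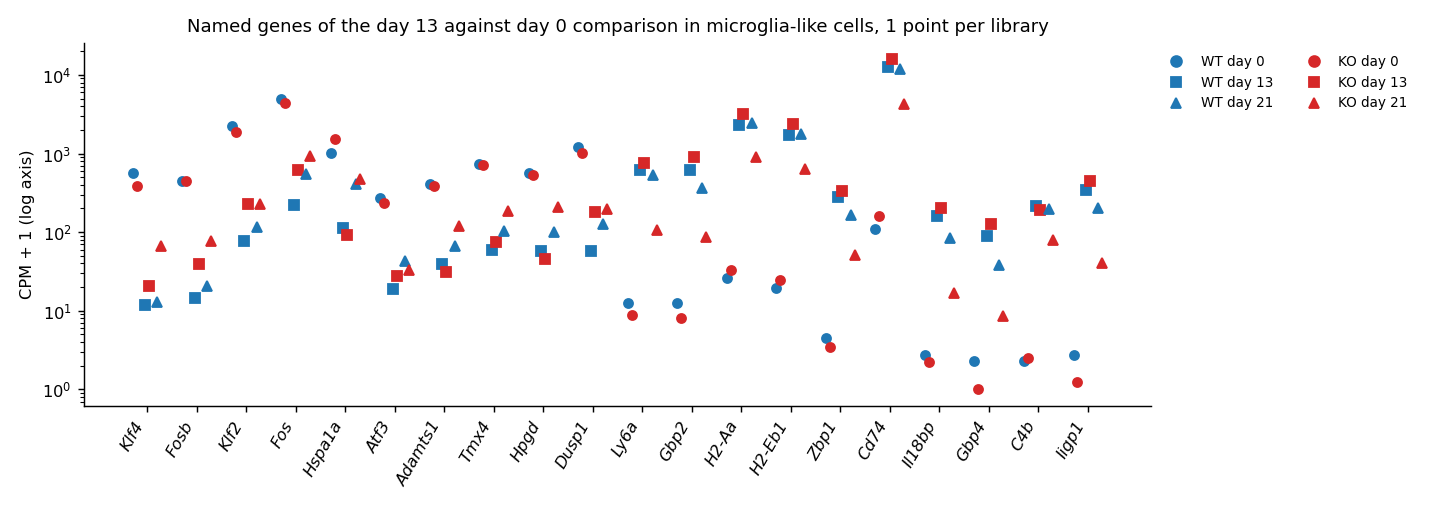
Level (CPM + 1, log axis) in microglia-like cells of the 20 named genes of the comparison of day 13 with day 0, with 1 point per library, circles for day 0, squares for day 13 and triangles for day 21, WT in blue and KO in red. Iigp1 rose by 8.95 and Klf4 fell by 4.84 on the log2 scale.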

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

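The tests of the Cd8a-led cluster, of short transcripts, of random pairs, of free microglial RNA, of cells held together and with cells of 2 lineages removed, and the counts over other splits of the libraries, were chosen only after the result was seen. The test on random pairs replaced an earlier one whose value had been seen and which would have excluded them at the assumed doublet rate.

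On day 21 the interferon-gamma, MHC class II and chemokine lists of microglia-like cells had median log2 ratios of KO to WT of -1.38, -1.41 and -1.05, opposite in sign to day 13, and the homeostatic list had 0.56, against -0.13 on day 13. RNA of monocyte/macrophage-like cells as the source of the interferon-gamma genes was excluded, since in WT microglia-like cells of day 21 their median reached 61.8% of its level in those cells and markers of those cells 1.21%, a ratio of 51.2, while RNA of T cells and the source of the chemokine genes were not tested. Different microglial clusters in the 2 libraries may account for part of the difference, but values within clusters cannot decide this. Clusters are formed from expression. Ccl12 and Ccl7, which lead the Ccl12-led cluster, belong to the chemokine list, and Olfml3 belongs to the homeostatic list. Comparing cells within such clusters can therefore shrink these differences in any case. Within the Ccl12-led and Olfml3-led clusters the interferon-gamma median was -0.17 and -0.68, MHC class II -0.12 and -0.50, chemokines 0.38 and -0.22, type I interferon 0.35 and -0.22 and homeostatic genes 0.29 and 0.14. This leaves open whether the cells of a cluster or the mix of clusters differed, and an effect of genotype, of the course of disease in these mice and of the single library cannot be told apart.

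Genes of cytotoxic lymphocytes fell over days in KO T-like cells, and Jun, Apoe and ribosomal protein genes rose. NK cell RNA as the source of the cytotoxicity list as a whole was excluded. In WT T-like cells its median gene reached 34.4% of its NK-like level and other NK markers 0.812%, a ratio of 42.3. A median over the list does not speak for single genes such as Gzma and Klrc1. Fewer cells of the Cd8a-led cluster may account for part of the fall, but removing that cluster cannot decide this. Its counterpart with doublets kept was led by Cd8b1, Cd8a, Gzmk, Nkg7, Gzmb, Ccl5 and Ctla2a. Of these, Cd8a, Gzmk, Nkg7, Ccl5 and Ctla2a are fallen genes, so leaving such cells out shrinks their difference in any case. Without that cluster 6 of the 16 genes still fell, among them Gzma and the myeloid genes Chil3 and Ngp. Ccl5 and Cd8a had smaller folds and did not pass, Tcrg-C2 had a larger one and did not pass, and Wdr95 was not tested. Fewer CD8 T cells cannot be told apart from lower levels within them. For the genes that rose, a gain of short transcripts in KO T-like cells is a candidate explanation: other genes under 600 bases had a median log2 ratio of 0.24 over days, against 0.01 for longer ones and a range of -0.05 to 0.06 for sets matched on expression, though only 3 of the 8 risen genes are that short, and over the classes compared short genes differed from longer ones by 0.111 to 0.268 on day 0, -0.02 to 0.141 on day 13 and 0.174 to 0.357 on day 21.

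Cells with both T and microglia markers formed a cluster of their own, 10.6% of WT and 3.57% of KO cells on day 21, and were left out of the comparisons. T cells of usual UMI content that took up free microglial RNA were excluded, since these cells held at least 2.01 times the median UMIs of T-like cells. This does not cover T cells rich in RNA. With doublets kept, a T-like cluster led by cell cycle genes had a median of 8396 UMIs. A T cell and a microglial cell held together would carry the sum of both, and the library farthest from this had 1.325 times the summed medians. Random pairs of cells in 1 droplet may also give this sum. The meeting of T and microglia markers in 1 droplet, relative to the product of their single counts, was set against the median of other marker pairs. It was at least 1.80 times that median in the libraries of days 13 and 21. In the WT and KO libraries of day 0 it was 2.68 and 0.969 times. This gap is too small to tell random pairs from pairs formed in the tissue. Against the share expected of random pairs at the assumed doublet rate, the cluster was 11.9 times as large in KO day 0, the lowest library. In KO day 13, the highest, it was 45.4 times as large. That rate was not measured here, so these values cannot exclude random pairs. No biological explanation was tested.

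The next values stand out because KO and WT differed in opposite directions on days 13 and 21. These differences between days were not tested, and 24 of 124 pairs of class and list met this. In microglia-like cells they were also the alternative phagocyte genes (-0.14, then 0.58) and oxidative phosphorylation (0.09, then -0.20). In T-like cells they were type I interferon (0.21, then -0.60), interferon-gamma (0.55, then -0.33), MHC class II (1.29, then -0.36) and cell cycle genes (0.17, then -0.65). Monocyte/macrophage-like cells had homeostatic microglia (-0.13, then 0.88), disease-associated microglia (0.07, then -0.13), MHC class II (-0.05, then 0.16), chemokine (0.44, then -1.87) and cytotoxicity genes (0.35, then -0.61). Conventional dendritic-like cells had interferon-gamma (0.24, then -1.14), chemokine (0.82, then -0.85) and NF-kB genes (0.54, then -0.50). Neutrophil-like cells had MHC class II (1.53, then -0.81), chemokine (1.08, then -0.74), Th1 (1.14, then -0.96), cytotoxicity (1.63, then -0.997) and dissociation genes (0.20, then -0.50), and B-like cells had homeostatic microglia genes (-0.55, then 2.11). The sign on 1 day turned under another setting for chemokines in microglia-like cells, for MHC class II and cell cycle genes in T-like cells, for homeostatic, MHC class II and cytotoxicity genes in monocyte/macrophage-like cells and for NF-kB genes in conventional dendritic-like cells, and the sign on both days for homeostatic genes in B-like cells.

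Shares that were on 1 side of equal on day 13 and on the other on day 21 had day 21 ratios of KO to WT of 4.69 for microglia-like, 0.391 for monocyte/macrophage-like and 0.667 for conventional dendritic-like cells. The ratio was 0.65 for all unnamed cells, 0.252 for the mixed T and phagocyte cluster, 0.396 for the mixed B and microglia cluster, 0.329 for all mixed clusters and 16.1 for the cluster led by Ttr, Lpl and Spp1. These differences between days were not tested either.

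Cells outside the named comparisons are listed where their share was above a floor of 3 counts. Any cluster of that size meets this rule, so it does not set these apart. Clusters led by the progenitor genes Elane, Mpo and Prtn3 held 6.28% of WT cells on day 21. The cluster led by Ttr, Lpl and Spp1 held 4.58% and that led by Ear2, Ace and Treml4 3.12% of KO cells on day 21. The mixed T and phagocyte cluster held 9.61% and the mixed T and microglia cluster 10.6% of WT cells on day 21. The mixed neutrophil and microglia cluster held 1.38% of WT cells and the mixed B and microglia cluster 1.45% of KO cells on day 13, and gamma-delta T-like cells were 0.783% of WT cells on day 21.

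The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In T-like cells 1 of the 10, the real one, gave 24 genes or more, and the highest other gave 4. In microglia-like cells 3 of the 10 gave as many as the real 3, and the split of both day 0 libraries and WT day 21 from the rest gave 323. In B-like cells 7 of the 10 gave as many as the real 1 and the highest other gave 73. In neutrophil-like cells all 10 gave as many as the real 0 and the highest other gave 117. The same split was the highest in microglia-like, B-like and neutrophil-like cells. It keeps both libraries of days 0 and 13 together, so with day as block it rests on KO against WT of day 21 alone and is not comparable with the real split. Of the 4 splits that part the libraries of every day, as the real one does, the highest other gave 1 gene in microglia-like, T-like and B-like cells and 5 in neutrophil-like cells.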

How the results depend on the processing

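The tests without the Cd8a-led cluster, with the cluster led by Ttr, Lpl and Spp1 counted as microglia-like, with cells of 2 lineages or of the highest doublet scores removed, with mixed T cells counted as T-like, and with shares over named cells were chosen only after the result was seen. Which results served as the main answers here was also settled after the list values were known. Pairing by replicate number was not possible because the groups share only number 1. KO and WT of a day were instead paired through the day block of the genotype tests. For monocyte/macrophage-like and conventional dendritic-like cells there are no values with a library left out, since 3 libraries leave no residual degrees of freedom.

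Of 9368 values of 782 results under the alternatives, 8615 kept their direction and their side of the threshold or stayed within counting error, 555 moved, 146 lost the threshold and 52 reversed. Among list medians within a day 4098 of 4477 held and 29 reversed, among genes within a day 2676 of 2804 held and 20 reversed, and among genes called over days by genotype 441 of 553 held, 109 lost the threshold and 3 reversed. Genes named by day kept their call in 1043 of 1080 values. Depth limits Il17a and Csf2 in T-like cells, every gene of the small day 0 classes, and Mir155hg in classes with fewer than 3 of its UMIs. The cause was not tested for any of the next values, except where fewer libraries or genes entered a fit or a scaling moved all genes. With doublets kept, the cells were clustered again. The day 13 libraries had 0 called doublets, so their values under this setting moved through new class borders alone.

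Counts of genes by genotype depended most on the setting. Microglia-like cells gave 0 with DESeq2, 0 with cells of 2 lineages removed, 0 with no day block, 6 with the Ttr-led cluster counted, 10 on days 13 and 21 alone, 16 with classes from each cell's own marker score and 74 with no low-count filter. T-like cells gave 0 with no day block, 47 with the highest doublet scores removed, 48 with doublets kept, 51 with cells of 2 lineages removed, 61 by marker score and 86 with no low-count filter. Monocyte/macrophage-like cells gave 1 with DESeq2 size factors, 2 at 5% mitochondrial UMIs, 1 with cells of 2 lineages removed and 48 with no low-count filter. Conventional dendritic-like cells gave 3 with cells of 2 lineages removed, 10 with the highest doublet scores removed and 60 with no low-count filter, and neutrophil-like cells 19 with that filter off. B-like cells gave 0 with DESeq2, 0 with no day block, 2 at 2 times the resolution, 3 with doublets kept, 4 at 5% mitochondrial UMIs, 5 on days 13 and 21 alone, 6 with cells of 2 lineages removed and 27 with no low-count filter. Between days in microglia-like cells, DESeq2 called 1455 genes for day 13 against day 0, 650 for day 21 against day 0 and 76 for day 21 against day 13, the last of which gave 607 with no low-count filter. Leaving out 1 library gave 14 to 129 genes in microglia-like, 15 to 115 in T-like, 5 to 91 in neutrophil-like and 11 to 23 in B-like cells, and 1275 to 4388, 563 to 1917 and 104 to 1360 for the 3 comparisons of days. In the comparisons of days, the lone library of a day was then assumed to vary like the others. In the genotype tests the lone library was fitted by its own day term, so that day left the contrast.

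The day 21 share ratio of microglia-like cells was 6.05 by marker score, 3.95 with cells of 2 lineages removed and 4.09 over named cells, that of T-like cells 0.277 with doublets kept and 0.183 with cells of 2 lineages removed, and that of monocyte/macrophage-like cells 0.488 by marker score and 0.329 with cells of 2 lineages removed. The day 13 ratio of T-like cells was 0.97 with mixed T cells counted.

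In microglia-like cells of day 21 the homeostatic median was 0.47 with TMM scaling, 0.51 without mitochondrial and ribosomal protein genes, 0.51 with the Ttr-led cluster counted and 0.42 by marker score. The interferon-gamma median was -1.12 by marker score and -1.07 with a pseudocount of 10, and the MHC class II median -1.46 with TMM scaling, -1.50 with the Ttr-led cluster and -0.89 with that pseudocount. In T-like cells the cytotoxicity median on days 13 and 21 was -0.45 and -0.53 without the Cd8a-led cluster and -0.73 and -0.88 with doublets kept, and it was -1.40 on day 13 with cells of 2 lineages removed and -0.93 on day 21 by marker score. The chemokine median of monocyte/macrophage-like cells on day 21 was -1.47 with doublets kept. The median of genes with a miR-155 site in microglia-like cells was 0.027 on day 13 with 8-base sites, -0.021 on day 13 and 0.031 on day 21 with TMM scaling, and on day 21 0.087 by marker score and 0.094 at 50 CPM. In T-like cells it was 0.088 on day 21 with 8-base sites, 0.034 on day 13 and -0.022 on day 21 with TMM scaling, -0.02 on day 13 with doublets kept and -0.014 on day 21 by marker score. TMM scaling moved the median of all genes by -0.033 on day 13 and -0.084 on day 21 in microglia-like cells and by 0.02 and -0.059 in T-like cells, which is close to the moves of the site genes and of the homeostatic list, so those moves are a shift of all genes and say nothing of these genes themselves.

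Values that reversed are given with their day. Under TMM scaling this was MHC class II in B-like cells on day 21 (-0.063). Without the Cd8a-led cluster it was Cd4 in T-like cells on day 21 (-0.049). With cells of 2 lineages removed these were NF-kB genes, alternative phagocyte genes and Cst3 in T-like cells on day 13 (-0.039, 0.085 and -0.28), cytotoxicity genes in monocyte/macrophage-like cells on day 13 (-0.11), Gzma in neutrophil-like cells on day 21 (-3.24), MHC class II in NK-like cells on day 0 (-0.51) and Apoe by genotype in T-like cells (-0.19). With the highest doublet scores removed they were MHC class II in T-like cells on day 21 (0.75), Gzma in neutrophil-like cells on day 21 (-1.28) and MHC class II in NK-like cells on day 0 (-0.89). With doublets kept they were cell cycle genes and Cd81 in T-like cells on day 13 (-0.027 and -0.054), cell cycle genes in conventional dendritic-like cells on day 13 (0.55), chemokines in NK-like cells on day 21 (-0.018) and Klrk1 by genotype in T-like cells (0.16). At 2 times the resolution they were cell cycle genes and Cd81 in T-like cells on day 13 (-0.007 and -0.31), Slpi in conventional dendritic-like cells on day 13 (1.17), Gzma in neutrophil-like cells on days 13 and 21 (-1.46 and -0.36) and chemokines in NK-like cells on day 21 (-0.011).

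With classes from each cell's own marker score 29 values reversed. In T-like cells these were MHC class II on days 0 and 21 (0.23 and 0.068), cell cycle genes on day 13 (-0.51), complement and Th1 genes on day 21 (-0.37 and 0.027), Cst3 on days 13 and 21 (-0.14 and -0.004), Cd81 on days 13 and 21 (-0.13 and -0.22) and Apoe by genotype (-0.46). In microglia-like cells it was the chemokine list on day 13 (-0.085). In monocyte/macrophage-like cells they were homeostatic genes on day 13 (0.18), MHC class II on day 21 (-0.025) and Cebpb on day 21 (0.019), and in conventional dendritic-like cells cytotoxicity genes on day 13 (0.22), NF-kB genes on day 21 (0.023) and Slpi on day 13 (0.78). In neutrophil-like cells they were dissociation genes on day 0 (-0.001), alternative phagocyte genes on day 13 (0.14) and Gzma on days 13 and 21 (-1.82 and -2.53). In B-like cells they were homeostatic microglia genes on days 13 and 21 (0.29 and -0.67), complement genes on day 21 (-1.90), Xbp1 and Txndc5 on day 21 (0.50 and 0.42) and Ptprc on day 21 (-0.017), in NK-like cells chemokines on day 21 (-1.91) and in plasmacytoid dendritic-like cells interferon-gamma genes on day 13 (-0.055).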

Other observations

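The tests with cells of 2 lineages or of the highest doublet scores removed were chosen only after the result was seen.

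NK-like cells entered no genotype test, and their cell cycle genes went opposite ways on days 0 and 21. Their cytotoxicity genes were near equal on days 0 and 21, with median log2 ratios of KO to WT of -0.06 and 0.10 and 1 of 11 genes lower by 1.5-fold or more on each day. Cell cycle genes were lower in KO on day 0 (13 of 17, median -2.33) and higher on day 21 (9 of 18, median 0.58). Of all 7851 genes measured in this class on day 0, 1514 were 1.5-fold or more higher and 1633 lower. On day 21 these were 1490 and 1178 of 7376. MHC class II genes had medians of 2.58 on day 0 and -1.23 on day 21, and the day 0 median turned to -0.51 with cells of 2 lineages removed and to -0.89 with the highest doublet scores removed. The phosphatase gene Inpp5d, a known miR-155 target, had log2 ratios of 0.44 on day 0 and 1.002 on day 21. The site genes of miR-155 had a median at percentile 2.87 of matched sets on day 21, the lowest of all classes and days.

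Plasmacytoid dendritic-like cells could be compared on day 13 alone. Their chemokines were higher in KO, with 10 of 10 genes and a median log2 ratio of 1.63, as were interferon-gamma genes (7 of 14, median 0.85, which turned to -0.055 with classes from each cell's own marker score) and type I interferon genes (7 of 18, median 0.26). The published targets had a median of 0.40 at percentile 99.94, with 5 of 18 higher and 3 lower, and Socs1, Cebpb and Inpp5d had log2 ratios of 1.40, 1.12 and 0.76. Mir155hg had 0 UMIs in these cells in both libraries, with an upper bound of 7.53 CPM in WT. Cell cycle genes were lower (7 of 13, median -0.59). In B-like cells Socs1 had log2 ratios of -0.77 on day 13 and -2.61 on day 21, the latter from 8 UMIs in KO and 36 in WT.

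Homeostatic microglia genes were also higher in the KO library of day 21 in other classes, with medians of 2.11 in B-like, 1.21 in T-like, 1.004 in neutrophil-like, 0.88 in monocyte/macrophage-like and 0.68 in conventional dendritic-like cells. The B-like median turned to -0.67 with classes from each cell's own marker score. Microglia-like cells were 41.2% of the cells of that library. In microglia-like cells themselves the list had a median of 0.56.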
